A study of Mus musculus with 9 samples.

How the data were processed

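RNA was sequenced from penile tissue of rats in 3 groups of 3 libraries each. The Sham group had the surgery without injury of the major pelvic ganglia, the paired ganglia that carry the autonomic nerve supply of the penis. In the Injury group both ganglia were clamped. In the Sacral NC group the ganglia were clamped and sacral neural crest cells, derived from human pluripotent stem cells per the series title, were then transplanted. Tissue was collected 4 weeks later, per the series design text. Groups and replicate numbers were taken from the sample titles.

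The sources disagree about the organism. The organism field of the labels names mouse and the submitters' processing notes name the mouse build GRCm38.p6, while the titles and the tissue label name rats, and all 21124 gene identifiers in the tables are rat Ensembl identifiers, with 0 mouse identifiers. The tables were read as rat data. Gene symbols, chromosomes, starts and ends are those the deposited tables pair with each identifier, and the rat build behind them is not given in the sources used here. The submitters' processing notes name HISAT2 2.0.5, a read aligner. The counting tool, its strand setting and the annotation release are not given in the sources used here, so a gene that overlaps another or has near-identical copies has an uncertain count.

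The authors deposited 3 tables, one for each pair of groups. Each holds, per the file headers, the raw read count of every gene in the 6 libraries compared, with means of those counts over each group. Each table also holds the authors' own log2 fold change, a test statistic (a score with no fixed range) and a p-value with its adjusted p-value, per the file headers. The counts of a library that stands in 2 tables were compared, and 0 values differed. All 9 libraries were therefore joined into 1 matrix of counts. No row lacked a gene identifier, and 94 symbols stood on more than 1 gene. Total counts per library ran from 15442190 to 18283418. At this depth counting error is large for genes with few reads, so the folds of such genes are uncertain. Reads or scaled counts are given for some of these genes and not for all.

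Counts were tested with edgeR 4.0.16 in R 4.3.3, with the quasi-likelihood F-test (robust fit), TMM scaling and the edgeR default filter on low counts, which kept 15509 genes. All 9 libraries entered 1 fit with a mean per group and 6 residual degrees of freedom, so the groups share an estimate of the spread. A gene is called changed at a Benjamini-Hochberg adjusted p under 0.05. Log2 fold changes are given with the standard error (SE) from the F statistic, and levels as TMM-scaled counts with the SD over 3 libraries. Gene lists of cell type markers and pathways, 32 in all, were tested with camera in limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation between genes of 0.01, adjusted over the 32 lists. Camera with the correlation estimated for each list, and fry, served as alternatives. Camera asks whether a list changed more than the other genes. Fry asks whether its members changed at all, so passing fry does not show that a list stood out. These tests, the 32 lists and the naming rules were fixed before the data were examined, and tests or sets added later are said to be.

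The genes named were chosen by rule. For each comparison these are the 10 largest rises and the 10 largest falls among called protein-coding genes with a symbol that is no placeholder, a mean of at least 50 scaled counts in the higher group and no overlap between the libraries of the 2 groups. Where fewer passed, 5 a side were filled by the smallest p and given without a call. From each list described, up to 4 members with the smallest p are named. A fixed set of 19 genes of erectile, matrix and nerve biology was examined in all comparisons, and a part of its results is not reported here. For genes changed in both main comparisons, the 10 with the largest product of changes are named. The text prints a part of the genes these rules give, and that part was picked after their values were seen. Genes named outside these rules are said to be.

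Alternatives changed 1 choice at a time, except that the DESeq2 1.42.0 Wald test ran on the unfiltered counts with its own size factors and independent filtering, so filter and scaling changed with the tool. The others were RLE size factors, no low-count filter, a filter of at least 10 counts in every library of a group, the replicate number as a block, an added 2-fold threshold, only the 2 groups compared, and each library left out in turn. A covariate for the skeletal muscle score (the mean log2 CPM of 19 muscle genes), leaving out the 4 libraries with over 0.1 % of reads in skeletal muscle genes, and scaling without collagen genes were added after seeing the data. The planned pseudocount and low-value filters for normalized values did not apply to counts.

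The fits were tested on simulated counts drawn from the means, dispersions and library sizes of these data. In the Injury against Sham simulation edgeR recovered 54.0 % of the genes changed 2-fold and 84.0 % of those changed 4-fold, with 2.1 % false calls among its calls over 15358 genes. For Sacral NC against Injury these shares were 61.5 %, 93.5 % and 3.1 %, and for Sacral NC against Sham 40.0 %, 90.0 % and 8.5 %. DESeq2, over all 15509 simulated genes, made 19.8 %, 12.6 % and 22.3 % false calls in the same 3 simulations. The simulated genes were drawn independently of each other, so the simulations do not check the list test for lists of correlated genes.

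The labels do not say that libraries of a group came from separate animals, so the p-values measure the spread between these libraries. Pairs of libraries within a group differed by a chi-square of 13.7 to 111 per degree of freedom over genes, so no library was a copy of another in its group. Pairs across groups were not compared. Reads from the human graft cannot be separated in counts assigned to rat genes and were not analysed here.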

Results

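Messenger RNA of rat penile tissue was counted in 9 libraries, 3 each from the Sham, Injury and Sacral NC groups, 4 weeks after surgery. Total counts were 17191109, 16687550 and 16164575 in the Sham libraries, 15924740, 16959134 and 18283418 in the Injury libraries, and 16693922, 15442190 and 15898210 in the Sacral NC libraries. Collagen genes took 17.0 % ± 1.78 of all counts in Injury (SD, n = 3), against 4.12 % ± 0.377 in Sham and 3.70 % ± 1.53 in Sacral NC. Col1a1, the alpha 1 chain of type I collagen, alone took 8.07 % ± 0.73 of the counts in Injury (SD, n = 3), against 1.36 % ± 0.247 in Sham and 1.28 % ± 0.787 in Sacral NC. The libraries also differed in skeletal muscle content without following the groups. Genes of the skeletal muscle list took 1.01 % of the counts in Sham 1, 0.229 % in Injury 1, 2.85 % in Injury 2 and 0.265 % in Sacral NC 2, and between 0.006 % and 0.016 % in the other 5 libraries. Acta1, skeletal muscle actin, had 124332 reads in Injury 2 and 210 in Injury 3. The first principal component, with 49.8 % of the variance, placed these 4 libraries and Injury 3 on 1 side and the other 4 libraries on the other.

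**Figure D1:**
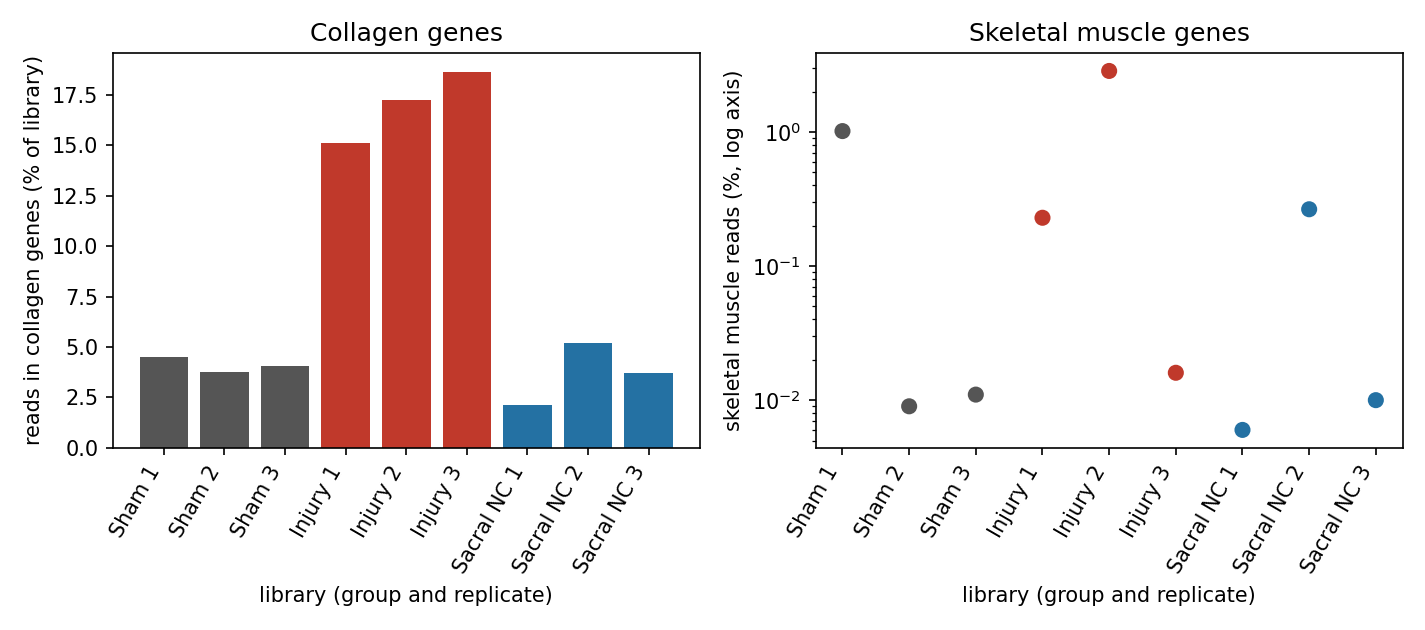
Left, the share of each library's reads in collagen genes, in percent, with 1 bar per library coloured by group, and right, the share of reads in the skeletal muscle list, in percent on a log axis, with 1 point per library. The 3 Injury libraries hold 15.1 %, 17.3 % and 18.6 % collagen reads, while muscle reads are above 0.1 % in 4 libraries spread over all 3 groups.

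The first comparison, Injury against Sham, asks what clamping of the ganglia did to RNA of the penis. By camera with a preset correlation, the matrix and cell cycle lists were higher after clamping, and the endothelial and neutrophil lists were lower. None of these 4 passed with the correlation estimated from the data (adjusted p = 0.202, 0.165, 0.165 and 0.38 with an estimated correlation). All 4 passed by fry, the other alternative (adjusted p = 0.00492, 0.00318, 0.00318 and 0.0153), which passed 6 of 32 lists here against 14 by camera. Col1a1 (ENSRNOG00000003897, chromosome 10, 79883622 to 79900624) rose 7.18-fold, from 208000 ± 39020 scaled counts in Sham to 1493000 ± 205800 in Injury (SD, n = 3 each). Its log2 change was 2.84 ± 0.43 (SE, adjusted p = 0.0143 by the edgeR quasi-likelihood test). Obp3 (ENSRNOG00000065108, chromosome 5, 74842316 to 74845757), a secreted lipocalin, fell from 3093 ± 821 to 388 ± 90.1 scaled counts (log2 change −3.00 ± 0.35, SE, adjusted p = 0.00746). In all, 687 of 15509 genes changed, 479 higher and 208 lower in Injury, and 329 of them by at least 2-fold. Over all tested genes, the libraries of the 2 groups did not overlap in 35.3 %, where chance gives 10 % on average. Genes vary together, so a single split can lie far from that average, and the spread was not computed. For Sacral NC against Sham, with 0 genes called, this share was 13.25 %. The call count rests on few libraries: it was 263, 69 and 21 without Sham 1, 2 and 3, 259, 166 and 113 without Injury 1, 2 and 3, and 1329 without Sacral NC 2. It was 1 without the 4 libraries rich in skeletal muscle, which leaves a single Injury library, 1456 with only the 2 groups in the fit, 1581 with DESeq2, and 267 with the replicate number as a block.

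Among the largest rises were 2 cartilage-type collagens. Col11a2 rose 9.83-fold (log2 change 3.30 ± 0.59) and Col2a1 8.37-fold (3.07 ± 0.52). The cartilage and bone list, which holds Col2a1, did not pass (median log2 change 0.036, 1 of 13 members called, camera adjusted p = 0.22). Prnd, a prion-like protein gene, rose 9.52-fold, the metalloproteinase gene Adam12 8.58-fold and the C1q-related gene C1qtnf3 7.73-fold. The mitotic genes Pbk and Troap rose 7.50- and 7.04-fold, Ube2c by a log2 change of 2.81, and Aldh1l2, a mitochondrial folate enzyme gene, 6.90-fold. The adjusted p of these 9 genes lay between 0.0102 and 0.0399 (edgeR). The largest falls were in the neutrophil genes S100a8, from 53.9 ± 37.3 to 0.766 ± 1.33 scaled counts, and S100a9, from 94.8 ± 68.8 to 2.57 ± 1.82. Tmprss4, a membrane serine protease gene, had 516 ± 484 scaled counts in Sham and 25.9 ± 28.4 in Injury, and the sulfotransferase gene Sult1c3 had 205 ± 174 and 13.2 ± 3.64. Duox2, which encodes a hydrogen peroxide producing oxidase, fell to 0.124 of its Sham level, its partner Duoxa2 to 0.0731, Clca5 to 0.145, the antimicrobial lipocalin gene Lcn2 to 0.155 and the efflux pump gene Abcb1b to 0.175. Annotated positions of Duox2 and Duoxa2 overlap, as do those of Obp3 and Mup4, so reads of each pair could be shared. Of the 56 genes named here as called, all kept their direction in every alternative run, and Ndufa4l2 and Obp3 alone stayed under the threshold whichever single library was left out.

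Of 37 tested extracellular matrix genes 19 were higher, 0 were lower and 18 did not pass, and 26 were higher and 1 lower when adjusted over the list alone. The list's median log2 change was 1.44 (camera adjusted p = 3.01e-16; adjusted p = 0.202 with an estimated correlation). Elastin, Eln, rose 4.69-fold, the collagen cross-linking enzyme gene Loxl2 4.02-fold, the collagen-binding protein gene Sparc 3.89-fold, Col5a1 3.73-fold and Col3a1 2.81-fold. Cell cycle genes rose in 14 of 26 members with 0 lower, and in 20 when adjusted over the list alone (median log2 change 1.42, camera adjusted p = 5.3e-15; adjusted p = 0.165 with an estimated correlation). Top2a, the DNA topoisomerase of dividing cells, rose 5.44-fold, Cenpf 4.65-fold, the mitotic motor gene Kif11 4.46-fold and the thymidylate synthase gene Tyms 1.74-fold. Skeletal muscle genes were higher in Injury on balance (median log2 change 1.68), with 0 of 19 members called over all genes or adjusted over the list alone (camera adjusted p = 0.0132; adjusted p = 0.793 with an estimated correlation). That list did not pass without Sham 2, Sham 3 or Injury 2, and its median was −1.08 without Injury 2 and 6.89 without Sham 1. With the muscle score in the fit, 24 of these 33 matrix and cell cycle genes stayed called, 17 of 19 matrix genes and 7 of 14 cell cycle genes. Without the 4 muscle-rich libraries 0 were called, with list medians of 1.54 and 0.99.

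Endothelial genes were lower. Of 22 members 11 fell and 0 rose, and 18 fell when adjusted over the list alone (median log2 change −0.69, camera adjusted p = 8.72e-13; adjusted p = 0.165 with an estimated correlation). Nos3, the endothelial nitric oxide synthase gene (chromosome 4, 10793834 to 10814166), fell to 0.406 of its Sham level (log2 change −1.30 ± 0.21, adjusted p = 0.0166 by edgeR). Sox17, a transcription factor of arterial endothelium, fell to 0.567, the VEGF receptor gene Kdr to 0.582 and Plvap to 0.604. Of the list of contraction signals, Edn1, the endothelin precursor, fell to 0.462, Ace to 0.475 and Ece1 to 0.648, while that list as a whole did not pass (camera adjusted p = 0.66). Pericyte genes rose in 2 of 11 members, also when adjusted over the list alone, Ndufa4l2 4.01-fold and Heyl 1.72-fold (camera adjusted p = 0.00472; adjusted p = 0.202 with an estimated correlation).

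Of the immune lists, those of neutrophils, inflammatory mediators, interferon response and myeloid cells were lower, while lymphocytes (0 of 7 called, camera adjusted p = 0.137) and mast cells (0 of 9, 0.889) did not pass. Neutrophil genes fell in 4 of 6 tested members, S100a8, S100a9, Lcn2 and the chemokine receptor gene Cxcr2, and in the same number adjusted over the list alone. The list had a camera adjusted p of 3.52e-04, and 0.38 with an estimated correlation. Cxcr2, at 0.196 of Sham, had 41, 13 and 26 reads in Sham and 5, 4 and 4 in Injury. Of the list's 13 genes with counts only 6 were tested. Mpo, Elane and Ngp, with at most 3, 1 and 9 reads in any library, were not, so neutrophil number was not measured. Inflammatory mediators fell in 3 of 25 members, the endothelial adhesion gene Sele to 0.345, the NF-kappa-B inhibitor gene Nfkbia to 0.569 and Il1r1 to 0.687, and in 6 adjusted over the list alone (camera adjusted p = 3.68e-06; adjusted p = 0.677 with an estimated correlation). The interferon list had 1 of 18 members called, Psmb9 at 0.507 of Sham, and 4 lower adjusted over the list alone (camera adjusted p = 0.0117; adjusted p = 0.793 with an estimated correlation). The myeloid, oxidative stress, ribosomal protein and immediate early lists were lower, and the smooth muscle and oxidative phosphorylation lists higher, with 0 members called in each, over all genes or adjusted over the list alone. Their camera adjusted p lay between 0.00402 and 0.0433, and all 6 had an adjusted p of 0.793 with an estimated correlation. The oxidative phosphorylation median of 0.17 was −0.055 without the 4 muscle-rich libraries, −0.08 without Injury 2, the library with the most muscle reads, and 0.04 with the muscle score in the fit, and the list passed in none of these, nor without Sham 3. The smooth muscle list did not pass with the muscle score, with RLE scaling, with scaling without collagen genes, or without Sham 2, Sham 3, Injury 1, Injury 2 or Sacral NC 3. The other 18 of the 32 lists did not pass, with camera adjusted p from 0.137 to 0.91. Of these, the nitric oxide and cGMP signalling list was lower by fry (adjusted p = 0.0165), with 1 of 24 members called.

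Single members of lists that did not pass also changed. The steroid-induced genes Fkbp5 and Tsc22d3 fell to 0.521 and 0.512 of Sham, and the lipase genes Pnpla2 and Lipe to 0.588 and 0.590. Ret, the signalling receptor of the GDNF family, rose 3.31-fold, its co-receptor gene Gfra1 1.58-fold and Ntrk2, the receptor of BDNF, 2.30-fold. Npy, neuropeptide Y of sympathetic nerves, had 36.8 ± 16.7 scaled counts in Sham and 2.91 ± 0.765 in Injury (SD, n = 3; adjusted p = 0.045 by edgeR). The keratin gene Krt13 rose 2.54-fold and Hoxc10 2.02-fold. The thymocyte antigen gene Thy1 and Col14a1, both fibroblast list members, rose 2.21- and 2.67-fold. Only 4 of the 15 fibroblast genes lay above 0, with a median log2 change of −0.25 (camera adjusted p = 0.889). Mup4 of the urinary protein family fell to 0.133, with only 4, 2 and 8 reads in Injury.

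Several genes of erectile function and nerve supply did not pass in this comparison. The log2 change was −0.04 ± 0.59 for Nos1, the neuronal nitric oxide synthase gene, −0.20 ± 0.12 for Gucy1a1, 0.09 ± 0.10 for Gucy1b1, 0.35 ± 0.48 for Pde5a and 0.29 ± 0.21 for Prkg1 (SE). It was 0.32 ± 0.52 for Acta2, 0.23 ± 0.60 for Myh11, −0.13 ± 0.18 for Tgfb1 and 0.38 ± 0.22 for the Schwann cell gene S100b. The growth factor genes Bdnf and Gdnf had log2 changes of −2.01 ± 0.60 and 0.98 ± 0.87, with adjusted p of 0.0987 and 0.543 (edgeR). Both had few reads, Bdnf 13, 16 and 10 in Sham and 4, 1 and 3 in Injury. Gdnf had 12, 1 and 10 in Sham and 17, 9 and 13 in Injury. Th, Vip and Chat, markers of adrenergic and cholinergic nerves, had at most 5, 3 and 14 reads in any library and were not tested.

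**Figure D2:**
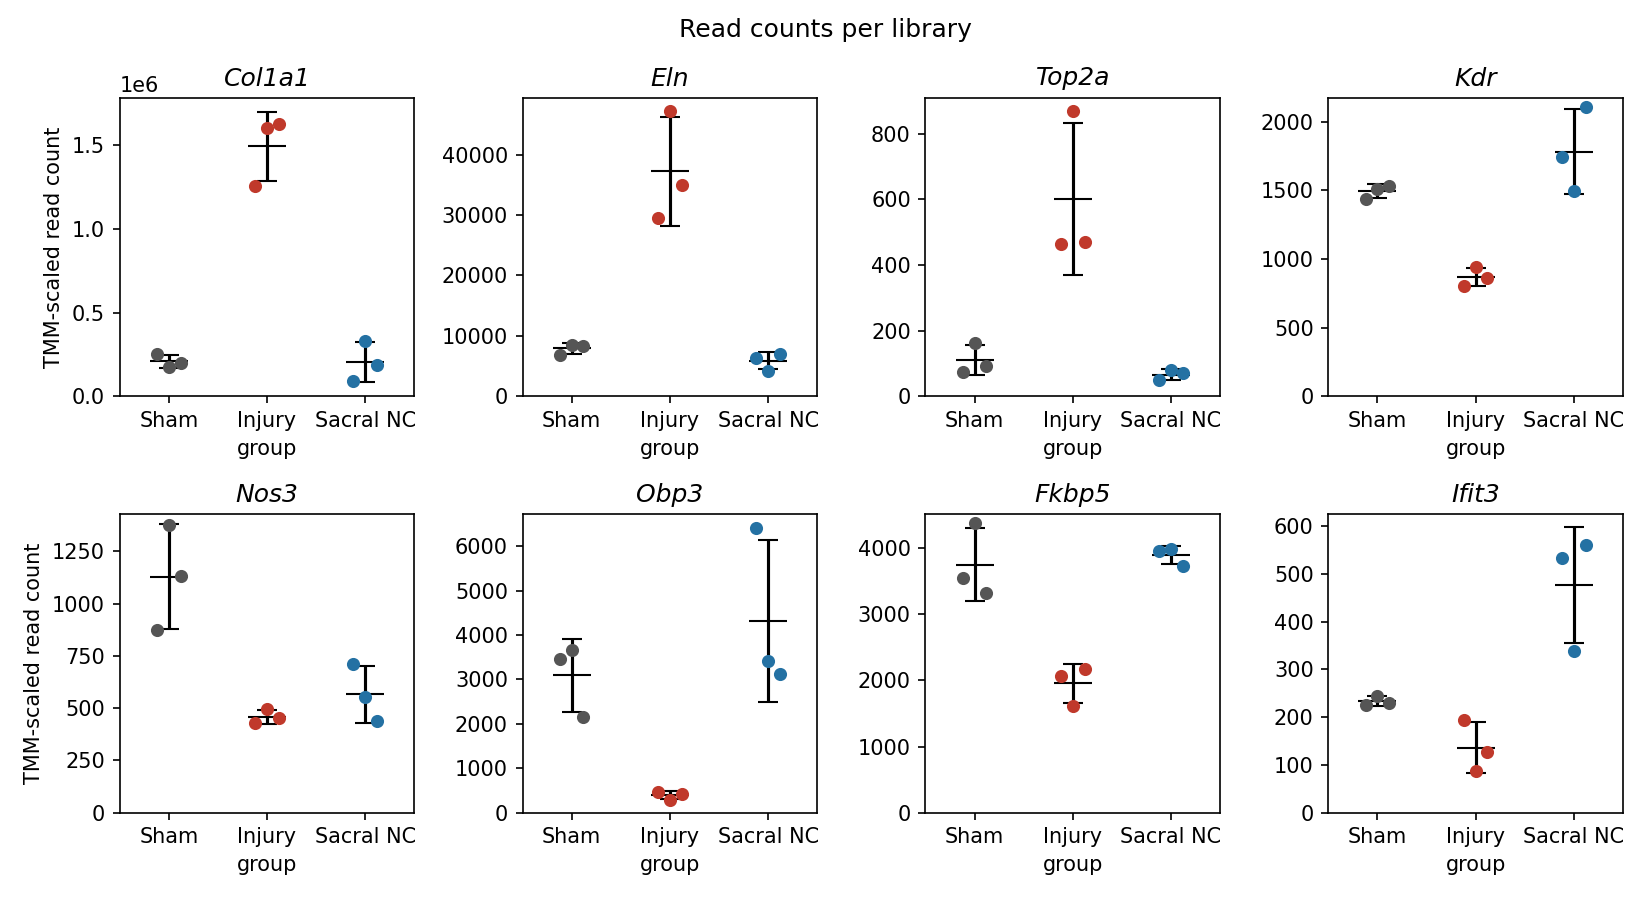
TMM-scaled read counts of 8 genes in each library (points), with the group mean and SD (horizontal line and bars, n = 3), on linear axes from 0. Col1a1, Eln and Top2a are highest in the 3 Injury libraries, Kdr, Obp3 and Fkbp5 are lowest there, and Nos3 averages 459 in Injury and 567 in Sacral NC against 1129 in Sham.

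The second comparison, Sacral NC against Injury, asks what differed with transplantation after clamping. The sample titles name no mock transplantation in Injury, so effects of the cells and of the procedure cannot be told apart. By camera with a preset correlation, the matrix and cell cycle lists were lower in transplanted rats, and the endothelial and interferon lists were higher. None of these passed with the correlation estimated (adjusted p = 0.217, 0.178, 0.217 and 0.352 with an estimated correlation). All of them passed by fry (adjusted p = 0.00379, 0.00122, 0.00379 and 0.0158), which passed 9 of 32 lists here against 13 by camera. Col2a1 fell to 0.0461 of its Injury level (log2 change −4.44 ± 0.58, SE, adjusted p = 0.00717 by edgeR), and Col1a1 to 0.137 (−2.86 ± 0.43, adjusted p = 0.00957). Col2a1 had only 2, 12 and 7 reads in Sacral NC, so the size of its fall is uncertain. Fcgr3a, an Fc receptor gene of natural killer and myeloid cells (chromosome 13, 83249872 to 83259921), rose from 39.4 ± 10.8 to 737 ± 481 scaled counts (SD, n = 3 each; adjusted p = 0.00885). In all, 1080 of 15509 genes changed, 506 higher and 574 lower in Sacral NC, 515 of them by at least 2-fold. Over all tested genes, the libraries of the groups did not overlap in 26.4 %, where chance gives 10 % on average with a spread that was not computed. The count was 705 and 495 without Sham 1 and 3, 470, 417 and 307 without Injury 1, 2 and 3, and 285, 3574 and 476 without Sacral NC 1, 2 and 3. It was 463 with the muscle score as a covariate, 59 without the 4 muscle-rich libraries, 239 with only the 2 groups in the fit, 2275 with DESeq2, and 471 with the replicate number as a block.

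Among the largest falls, Troap fell to 0.0603 of Injury, Depdc1 to 0.098, the kinetochore gene Cenpt to 0.0992, the spindle checkpoint gene Bub1b to 0.101, Pbk to 0.109, and Top2a and Fam83d to 0.111 each, with Adam12 at 0.0818 and C1qtnf3 at 0.101. Some of these folds rest on few Sacral NC reads: 3, 8 and 3 for Troap, 5, 5 and 7 for Cenpt, and 2, 20 and 14 for Bub1b. Among the largest rises, Fcrl1, an Fc receptor-like gene of B cells, had 0.361 ± 0.626 scaled counts in Injury and 530 ± 668 in Sacral NC. The natural killer receptor genes Ly49i7, Klra1 and Klra5 had 109 ± 85.9, 116 ± 84.4 and 135 ± 134 in Sacral NC against 1.81 ± 3.13, 2.84 ± 3.33 and 5.37 ± 2.08 in Injury. These receptors, like Fcgr3a, Mup4 and Obp3, belong to families of similar genes, so their separate counts are uncertain. Cxcl13, a chemokine that attracts B cells, rose 13.1-fold, Rgs1 11.7-fold and Slc11a1, a metal transporter of macrophages, 10.8-fold. Mup4 and Obp3, whose annotated positions overlap, rose 13.3- and 11.1-fold, with only 4, 2 and 8 Mup4 reads in Injury. Of the 76 genes named as called in this comparison, 32 stayed under the threshold whichever single library was left out, among them Col1a1, Top2a, Kdr, Fcgr3a and Obp3.

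Matrix genes fell in 22 of 37 members with 0 higher, and 28 were lower and 2 higher when adjusted over the list alone (median log2 change −1.41, camera adjusted p = 1.55e-14; adjusted p = 0.217 with an estimated correlation). Eln fell to 0.158, Loxl2 to 0.197, Col5a1 to 0.251, Col3a1 to 0.274 and the basement membrane collagen gene Col4a1 to 0.360. Cell cycle genes fell in 19 of 26 members, and in 23 when adjusted over the list alone (median log2 change −2.00, camera adjusted p = 1.1e-18; adjusted p = 0.178 with an estimated correlation). Cenpf fell to 0.122, Tpx2 to 0.163 and the replication licensing gene Mcm5 to 0.447. Skeletal muscle genes were lower on balance (median log2 change −3.53) with 0 of 19 members called (camera adjusted p = 0.0047; adjusted p = 0.834 with an estimated correlation), and smooth muscle genes likewise with 0 of 24 called (camera adjusted p = 0.00788; adjusted p = 0.849 with an estimated correlation). The skeletal muscle list did not pass without Injury 2 (median −0.52) or Sacral NC 3, and its median was −6.53 without Sacral NC 2. The smooth muscle list did not pass without Sacral NC 1 (median 0.001) or 3, and its median was −1.21 without Sacral NC 2. With the muscle score in the fit 19 matrix and 16 cell cycle genes were lower. Pericyte genes fell in 2 of 11 members, Ndufa4l2 to 0.276 and Heyl to 0.652, and 4 were lower and 1 higher adjusted over the list alone (camera adjusted p = 0.00295; adjusted p = 0.217 with an estimated correlation).

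Endothelial genes rose in 10 of 22 members, and in 17 when adjusted over the list alone (median log2 change 0.58, camera adjusted p = 3.42e-10; adjusted p = 0.217 with an estimated correlation). Kdr rose 2.05-fold, the angiopoietin receptor gene Tek 1.94-fold, Emcn 1.82-fold and the transcription factor gene Erg 1.61-fold. Nos3 did not pass: its log2 change was 0.31 ± 0.20 (SE, adjusted p = 0.366 by edgeR). Edn1 rose 2.78-fold, Rock1 1.62-fold and Ece1 1.53-fold, while the list of contraction signals did not pass (camera adjusted p = 0.778). Interferon genes rose in 9 of 18 members, and in 15 when adjusted over the list alone (median log2 change 1.14, camera adjusted p = 9.01e-10; adjusted p = 0.352 with an estimated correlation). Ifit3 rose 3.51-fold, Usp18 2.25-fold, Gbp5 2.13-fold and the viral RNA sensor gene Ifih1 1.84-fold. Myeloid genes had 0 of 24 members called over all genes and 18 higher when adjusted over the list alone (median log2 change 1.83, camera adjusted p = 1.9e-05; adjusted p = 0.717 with an estimated correlation). The myeloid score (mean log2 CPM) was 5.86, 4.01 and 6.76 in Sacral NC 1, 2 and 3 and 4.00, 4.29 and 4.56 in Injury 1, 2 and 3, so Sacral NC 2 lay within the Injury range. Inflammatory mediators rose in 4 of 25 members, Ccl4 6.29-fold, Nfkbia 2.66-fold, Icam1 1.66-fold and Sele 1.65-fold, and in 11 adjusted over the list alone. Their camera adjusted p was 3.25e-05, and 0.573 with an estimated correlation. Ccl4 had only 4, 4 and 5 reads in Injury and 42, 13 and 34 in Sacral NC, so its fold is uncertain.

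Ribosomal protein genes rose in 5 of 32 members, and in 29 when adjusted over the list alone (camera adjusted p = 1.62e-11; adjusted p = 0.573 with an estimated correlation), with Rpl34 1.86-fold, Rpl37 1.83-fold, Rps23 1.82-fold and Rps24 1.66-fold higher. Immediate early genes rose in 4 of 22 members, Klf4 2.16-fold, Klf6 1.74-fold, and Klf2 and Zfp36 by log2 changes of 1.58 and 1.32, and in 10 adjusted over the list alone (camera adjusted p = 1.9e-05; adjusted p = 0.48 with an estimated correlation). Steroid action genes rose in 3 of 16 members, Tsc22d3 2.90-fold, Fkbp5 1.99-fold and the mineralocorticoid receptor gene Nr3c2 1.87-fold, also when adjusted over the list alone (camera adjusted p = 0.0103; adjusted p = 0.48 with an estimated correlation). Oxidative stress genes rose in 2 of 22 members, Sod1 1.48-fold and Gpx4 1.36-fold, and in 5 adjusted over the list alone (camera adjusted p = 6.52e-04; adjusted p = 0.639 with an estimated correlation). The other 19 lists did not pass, with camera adjusted p from 0.0669 to 0.983. Of these, the nitric oxide and cGMP signalling list was higher and the cartilage and bone list lower by fry (adjusted p = 0.0158 and 0.035).

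Single members of lists that did not pass also changed, 1 higher and 3 lower of 31 neurotrophic genes (camera adjusted p = 0.778) and 1 higher and 2 lower of 20 neuronal genes (camera adjusted p = 0.806). Ret fell to 0.319 of Injury (log2 change −1.65 ± 0.33, SE, adjusted p = 0.0274 by edgeR), Ntrk2 to 0.488, Gfra1 to 0.658 and Ddc to 0.297. Npy had 2.91 ± 0.765 scaled counts in Injury, from 2 or 3 reads per library, and 32.3 ± 23.6 in Sacral NC (SD, n = 3; adjusted p = 0.0429 by edgeR), and Il6st rose 1.59-fold. Gsn rose 2.53-fold, Ndrg1 2.40-fold, Bmp4 2.06-fold, Pnpla2 1.73-fold and Lipe 1.57-fold, and the apoptosis genes Pmaip1 and Bcl2l11 rose 2.71- and 1.99-fold. Thy1 fell to 0.445, Col14a1 to 0.387 and Krt13 to 0.351. The log2 change did not pass for Nos1 (0.19 ± 0.59), Gucy1a1 (0.27 ± 0.12), Gucy1b1 (0.01 ± 0.10), Pde5a (−0.17 ± 0.48), Prkg1 (−0.27 ± 0.21), Acta2 (−0.48 ± 0.52) or Myh11 (−0.34 ± 0.60). Nor did it for Tgfb1 (0.43 ± 0.18), S100b (0.01 ± 0.22), Bdnf (0.79 ± 0.66) or Gdnf (−1.35 ± 0.91).

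The design also asks how far injury changes were turned back after transplantation. Of the genes changed in Injury against Sham, 494 changed in the opposite direction in Sacral NC against Injury, 353 that were higher and 141 that were lower in Injury, and 0 changed further in the same direction. The 353 were 73.7 % of the 479 Injury-higher genes and the 141 were 67.8 % of the 208 Injury-lower genes. The 10 with the largest product of changes were Col2a1, Troap, Adam12, Mup4, Obp3, C1qtnf3, Pbk, Col11a2, Fam83d and Col1a1. Col1a1 had 205200 ± 119600 scaled counts in Sacral NC and 208000 ± 39020 in Sham, and Obp3 4316 ± 1824 and 3093 ± 821 (SD, n = 3). Nos3, at 567 ± 136 in Sacral NC, stayed closer to its Injury level of 459 ± 33.0 than to its Sham level of 1129 ± 251. Both comparisons use the Injury libraries, so opposite signs arise by chance. Independent lists of these sizes would share 17.7 and 6.79 genes, and simulated unchanged groups shared 0 in 20 simulations, which says nothing of the overlap that shared libraries give where many genes are called. The correlation of the fold changes over all genes, which are not independent replicates, was −0.81 against −0.50 in the simulations, and the covariance was −0.403 against −0.092, a difference of −0.311. With 3 Injury libraries the shared group could not be split into parts of at least 2, so part of the excess may come from it. The count was 210, 63 and 20 without Sham 1, 2 and 3, 213, 127 and 90 without Injury 1, 2 and 3, and 226 and 1039 without Sacral NC 1 and 2. It was 293 with the muscle score in the fit, 1 without the 4 muscle-rich libraries, 214 with the replicate block and 1059 with DESeq2.

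**Figure D3:**
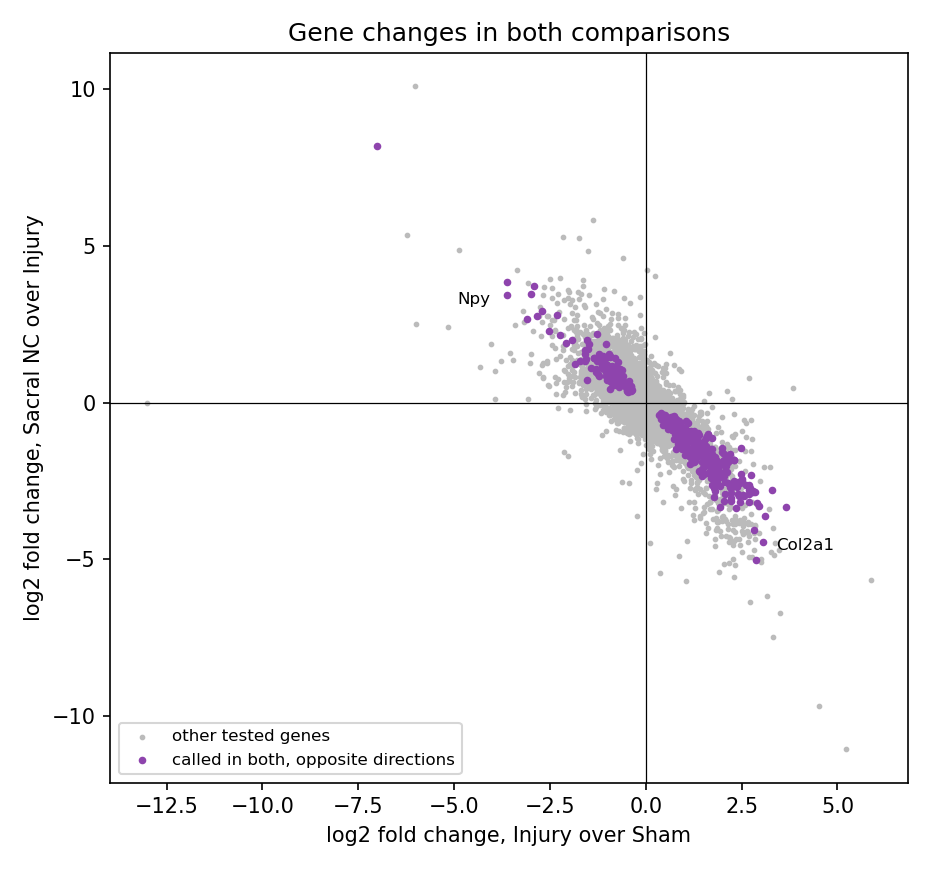
Log2 fold change of each of 15509 tested genes in Injury over Sham (horizontal axis) and Sacral NC over Injury (vertical axis), on log2 scales. The 494 genes called in both with opposite signs are coloured, 353 in the lower right and 141 in the upper left, and both axes share the Injury libraries.

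The third comparison, Sacral NC against Sham, asks what differed between transplanted and unclamped rats. No gene passed with edgeR (0 of 15509, smallest adjusted p = 0.16). At an unadjusted p under 0.05 there were 1232 genes, and DESeq2 called 61, 41 higher and 20 lower in Sacral NC. The authors' deposited table, which holds the same counts, also has 61 and so is no separate support. Without Sacral NC 2, the muscle-rich library of its group, edgeR called 106 genes, 80 higher and 26 lower, and 1 without Sham 2. The genes with the smallest p that were higher in Sacral NC, given without a call, were the interferon-induced genes Rtp4 (2.79-fold), Usp18 (2.82-fold) and Oas1f (2.77-fold, ENSRNOG00000033220, 1 of 2 genes with that symbol), Depp1 (2.70-fold) and Fcgr3a (18.9-fold). On the lower side these were Lcn2 (0.265 of Sham), Exoc3l2 (0.455), Sptbn5 (0.465), Rem1 (0.564) and the endothelial gene Plvap (0.681). Col1a1 differed by a log2 change of −0.02 ± 0.40, Col3a1 by −0.38 ± 0.29 and Nos3 by −0.99 ± 0.20 (SE), with adjusted p of 0.992, 0.737 and 0.575 (edgeR).

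Of the lists, 8 passed by camera in Sacral NC against Sham, with 0 members called over all genes in each. By fry 0 of 32 lists passed here. Interferon genes were higher (median log2 change 0.85, camera adjusted p = 1.18e-09; adjusted p = 0.74 with an estimated correlation), with 5 of 18 higher when adjusted over the list alone. Its members with the smallest p after Usp18 were Mx2 (3.33-fold), Ifit3 (2.05-fold) and Oas1a (2.69-fold). Ribosomal protein genes were higher (median log2 change 0.43, camera adjusted p = 5.16e-13; adjusted p = 0.848 with an estimated correlation), as were immediate early genes (9.3e-05 and 0.848 with an estimated correlation), oxidative phosphorylation genes (0.0104 and 0.99) and myeloid genes (0.0409 and 0.99). Cell cycle genes were lower (median log2 change −0.44, camera adjusted p = 1.53e-05; adjusted p = 0.74 with an estimated correlation), as were neutrophil genes (4.07e-04 and 0.74) and Schwann cell genes (4.95e-04 and 0.885). The other 24 lists, the matrix and endothelium lists among them, did not pass, with camera adjusted p from 0.0689 to 0.991. Adjusted over the list alone, 4 neutrophil genes were lower and 1 higher, and 1 immediate early gene was higher. Of lists that did not pass, 3 endothelial genes and 1 nitric oxide gene were lower, and 2 inflammatory mediators were higher and 3 lower, also adjusted over the list alone. Without Sacral NC 3 the myeloid list no longer passed (median log2 change 0.06, camera adjusted p = 0.275), and its camera direction turned.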

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

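The muscle covariate, leaving out the 4 muscle-rich libraries and scaling without collagen genes were chosen only after the data were seen. For Injury against Sham, 687 genes became 267 with the replicate block, 1 without the muscle-rich libraries, 1581 with DESeq2, 1456 with only the 2 groups and 329 with the 2-fold threshold, and 21 to 1329 with 1 library left out. For Sacral NC against Injury, 1080 became 471 with the replicate block, 463 with the muscle covariate, 59 without the muscle-rich libraries, 2275 with DESeq2, 239 with only the 2 groups and 515 with the 2-fold threshold, and 285 to 3574 with 1 library left out. For Sacral NC against Sham, 0 by edgeR (1232 at an unadjusted p under 0.05) became 61 with DESeq2, and 0 to 106 with 1 library left out. The recovery count of 494 became 214 with the replicate block, 293 with the muscle covariate, 1 without the muscle-rich libraries, 1059 with DESeq2 and 237 with the 2-fold threshold, and 20 to 1039 with 1 library left out. Of the lists, 14, 13 and 8 passed, and 0, 0 and 0 with an estimated correlation, 6, 9 and 0 with fry, and 13, 17 and 13 without the muscle-rich libraries; with 1 library left out the ranges were 9 to 15, 11 to 17 and 7 to 13. The replicate numbers did not pair the libraries: correlations of same-numbered deviations ran from −0.550 to 0.620, and 3 of 9 libraries correlated best with their own number. Without the muscle-rich libraries, which leaves 1 Injury library assumed to vary like the others, fewer samples are tested; the cause of the other shifts was not tested. Of 56 genes named as called in Injury against Sham, 55 kept their call with RLE, 49 with no filter, 33 with the block, 43 with the muscle covariate, 0 without the muscle-rich libraries and 52 with only the 2 groups, and 2 to 55 with 1 library left out. Of 76 in Sacral NC against Injury these were 76, 70, 47, 46, 8 and 28 (1 not tested with only the 2 groups), and 36 to 76. No gene named as called turned its direction in an alternative that tested it. Directions turned for some lists and for genes that had not passed, given here as log2 changes. With the muscle covariate the skeletal muscle list was 0.244 in Injury against Sham and −0.009 in Sacral NC against Injury, where the list test turned, Nos1 0.035 in the former and Pde5a 0.048 in the latter. Without the muscle-rich libraries oxidative phosphorylation was −0.055 and Tgfb1 0.009 in Injury against Sham, and Gucy1b1 −0.244 and S100b −0.255 in Sacral NC against Injury. Nos1 kept its direction there but moved to −0.980 in Injury against Sham and to 1.429 in Sacral NC against Injury. In the last comparison Gucy1b1 and S100b were −0.017 and −0.008 with RLE, −0.021 and −0.013 with no filter, −0.013 and −0.005 with scaling without collagen, −0.014 and −0.004 with DESeq2, and −0.011 and −0.003 with only the 2 groups. Col1a1 was 0.002 in Sacral NC against Sham with scaling without collagen. With 1 library left out, the skeletal muscle list ran from −1.077 to 6.888, oxidative phosphorylation from −0.076 to 0.299 and Nos1 from −0.267 to 0.262 in Injury against Sham. In Sacral NC against Injury, the skeletal muscle list ran from −6.526 to −0.516, the smooth muscle list from −1.206 to 0.001, Nos1 ran from −0.866 to 0.579, Gucy1b1 from −0.083 to 0.092, Pde5a from −0.934 to 0.159, Myh11 from −1.332 to 0.077 and S100b from −0.153 to 0.178. In Sacral NC against Sham, the myeloid list ran from 0.055, where the list test turned, to 1.299, and Col1a1 from −0.551 to 0.328. Genes with few reads, such as Npy in Injury, are limited by depth.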

Other observations

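The tests of skeletal muscle, collagen reads, growth genes and a single Sacral NC library, and the loci below, were chosen or worded only after related results were seen. The tests of myeloid content and of other splits were set before. The rule that a bound had to be passed by more than the median SE was added after a first run had shown the values, and it left the myeloid and single-library tests undecided where the first wording would have counted against both explanations.

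Imprinted genes of fetal and muscle growth, a set of 9 written after the main results were seen, were higher in Injury than Sham on balance. Their median log2 change was 0.80, 9 of 9 lay above 0, 6 by over 2 SE, and Mest, Peg3 and Grb10 passed, with log2 changes of 1.14 ± 0.26, 0.91 ± 0.21 and 0.77 ± 0.13 (SE, n = 3 each; adjusted p = 0.0492, 0.0492 and 0.0194 by edgeR). Igf2 differed by 0.01 ± 0.14, and H19 had 28788.6 scaled counts in Injury 2, the library richest in skeletal muscle, and 1071.6 in Injury 3. In Sacral NC against Injury, Grb10, Peg3 and Plagl1 were lower (log2 changes −0.77, −0.89 and −1.02, adjusted p = 0.0154, 0.0421 and 0.0481 by edgeR). The others did not pass, and of the set only Cdkn1c lay above 0 there (0.39, adjusted p = 0.581).

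Matrix and cell cycle genes were higher in Injury than Sham by camera (adjusted p = 0.202 and 0.165 with an estimated correlation), with 33 members called by edgeR. With the skeletal muscle score in the fit, 24 of these stayed called. The median log2 change of the 33 went from 1.90 to 1.77 (median SE 0.29 and 0.28), which argues against muscle content as the whole cause. For collagen genes the shares of reads per library also argue against it. They were 4.5 % and 5.2 % in the muscle-rich Sham 1 and Sacral NC 2, and 18.6 % in Injury 3, which had 0.016 % muscle reads. Of the 14 cell cycle members 7 lost the call, with a median of 2.07 before and 1.93 after while the median SE went from 0.36 to 0.41 and the residual degrees of freedom from 6 to 5. With scaling that left out collagen genes the cell cycle median was 2.11, which decides nothing, since collagen reads only lower the share of other genes. Growing tissue or younger animals in the Injury group may have contributed, as a hypothesis only: the growth gene median of 0.80 (0.68 with the muscle covariate) met limits set after part of the values was seen, ages are not in the labels used here, and regrowth after injury would give the same values. Such a difference would enter both comparisons with Injury, and so the recovery count.

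Interferon genes were higher in Sacral NC than Sham by camera, with a median log2 change of 0.85 and library scores of 4.89, 4.16 and 4.88 in Sacral NC against 3.63, 4.18 and 3.84 in Sham (mean log2 CPM). The list did not pass otherwise (adjusted p = 0.74 with an estimated correlation, 0.466 by fry), and no member passed over all genes, against 5 of 18 adjusted over the list alone. With the myeloid score in the fit the median was 0.49 (median SE 0.20), with 17 of 18 members above 0, so more myeloid cells in these libraries could account for part of it. Counts of whole tissue cannot tell this apart from higher levels within cells. The test itself was also undecided, since 0.49 lay within its SE of the bound, a fixed share of 0.85. Without Sacral NC 1, 2 or 3 the median was 0.56, 1.05 or 0.65, which leaves a share of a single library open as well. A response of the host to the human cells was not tested.

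The 6 libraries of a comparison can be split into 2 groups of 3 in 10 ways, the real one included, too few for a share under 0.05, and the counts of splits given here include the real one. Of these, 1 gave as many genes as Injury against Sham (687, highest other 0) and 1 as many as Sacral NC against Injury (1080, highest other 1). For Sacral NC against Sham edgeR called 0 genes (1232 at an unadjusted p under 0.05, 61 by DESeq2; highest other 4), so that all 10 splits gave as many and the count decides nothing. For the lists, 3 of 10 splits gave as many as the 14 of Injury against Sham (highest other 15), 5 of 10 as many as the 13 of Sacral NC against Injury (highest other 18) and 7 of 10 as many as the 8 of Sacral NC against Sham (highest other 16), so that counts of lists this large also came from mixed groups. For the recovery count, 1 of 100 splits drawn from 840, the real one, gave as many as 494. This does not exclude chance for recovery, since the count followed whether the Injury libraries stayed together. The highest other count, 475, came from the 1 drawn split that kept the Injury libraries together, and splits that broke them up gave at most 1, with 0 in 93 splits, so this test shows that the Injury libraries stood apart from the other 6 and not recovery as such.

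Or2b4, an olfactory receptor gene on chromosome 20, had 3065, 33 and 2351 reads in Injury 1, 2 and 3 and between 29 and 49 in the other 6 libraries. RGD1562420 on chromosome 6 had 2, 0 and 0 reads in Injury and between 111 and 352 in the other 6. Such a pattern also crossed the groups: Cycs on chromosome 18 had 87 reads in Sham 2, 94 in Sacral NC 2 and between 0 and 6 in the other libraries.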
